A study of Mus musculus with 2 samples.

How the data were processed

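Total RNA from the hippocampus of 2 adult male B6CASTF1/J mice, the first-generation cross of C57BL/6J and CAST/EiJ, was sequenced as 1 library per animal. Per the labels, the animals were 8 to 10 months old, 300 ng of RNA entered each library, the tissue was a layer of hippocampus, the library kit keeps the strand of the RNA, ribosomal RNA was reduced and ERCC spike-ins (synthetic control RNAs) were added. Replicate 1 was animal 2 and replicate 2 was animal 4. The labels give both tissue samples the same donor entry but different animal numbers. They define 1 group of 2 animals, so no comparison between groups was possible, and whether the animals shared a litter or a dissection day is not given in the sources used here.

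The authors deposited, for each library, a gene table and 2 transcript tables on the mm10 assembly with the GENCODE M21 annotation, per the submitters' processing notes. The gene table and the first transcript table have the column names of RSEM, and per the same notes they were made from an alignment of the reads to the transcriptome. The second transcript table has the column names of kallisto and was made from the read files. The program names and versions are not given in the sources used here. The deposited expected counts are estimated reads per gene or transcript, with shared reads divided among features by the program, and they are not scaled between libraries. The deposited TPM values are transcript abundances divided by effective length and scaled to the same sum in each library. The deposited percent values give each transcript's share of its gene's TPM. The deposited interval bounds of TPM are credible bounds, whose level is not given in the sources used here, and they carry no spread between animals. The deposited TPM of a gene can lie outside its own bounds. In replicate 1, Fth1 had 1500 TPM with bounds of 1391 to 1470, and mt-Co3 had 1078 TPM with bounds of 2176 to 3304. Calls made from the bounds are therefore not calls on the TPM values given beside them. The deposited estimated counts and TPM of the second table are per transcript and were summed per gene here. Its effective lengths were the same in both libraries for every transcript. In replicate 1, the median shortening was 248 bases over its long transcripts alone, against 100 bases in the gene table. The latter median covered shorter features too, so the 2 medians are over unlike sets. All 55536 annotated genes of the gene table matched GENCODE M21.

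The total of expected counts was 23458117 in replicate 1 and 29584307 in replicate 2, of which 23408838 and 29512441 were on annotated genes. The second table held 25213972 and 31237997 estimated counts. Shares of counts in 1 library are given with 95% Wilson intervals. These intervals, the TPM bounds and the limit that a count of 0 allows, which is 3 counts per library, cover counting error only, because reads without molecular identifiers are not independent molecules.

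Levels are the mean and SD of TPM over the 2 animals. Paralogs were called different where the TPM bounds of one lay above those of the other in both libraries. A gene was detected where TPM was 1 or more. The Pearson and Spearman correlations between libraries were taken across genes on log2(TPM + 1). Genes are not independent replicates, so the correlations have no p. The difference between the 2 libraries was tested with edgeR 4.0.16 in R 4.3.3 on expected counts rounded to whole numbers. Tested genes had CPM (counts scaled to a common library size) of 1 or more in at least 1 library. The fit used TMM scaling, a design of an intercept alone and the trended dispersion. The residual deviance of each gene was set against chi-square with 1 degree of freedom, and Benjamini-Hochberg adjusted p under 0.05 was the threshold. This test has 1 residual degree of freedom per gene, and its p-values compare these 2 libraries, not conditions. With 2 animals, no exact permutation test can reach p under 0.05. Log2 ratios are of replicate 2 over replicate 1 in TMM-scaled CPM with a prior count of 2. Where 1 library had no reads for a gene that passed the test, the fold is given as a lower bound against 3 counts in that library.

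On simulated libraries with the means of these data and 200 changed genes, tested over 16123 genes in 5 runs, the test recovered 6.4% of genes changed 2-fold, 65.6% of those changed 4-fold, 85.6% at 8-fold and 98.4% at 32-fold, with 2.6 false calls per run. Simulated libraries without changed genes gave 0 calls, and a simulated coefficient of variation of 0.191 was recovered as 0.191. Changes of 2-fold were therefore mostly below what 2 libraries can show. The simulated counts held no error from dividing shared reads among features, so false calls from that source are not covered. In the runs with changed genes, each gene was also simulated with the trended dispersion that the test assumes. The number of false calls therefore follows largely from construction, and calls of genes that vary more than the trend are not covered. The runs without changed genes used a common dispersion.

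Before the data were examined, 39 gene lists were fixed: markers of hippocampal subfields, other cell types and neighbouring tissues, receptor families, and groups of genes that respond to activity, stress or time of day. The median log2 ratio of each list with at least 4 members of 10 or more reads was placed among 10000 random lists of the same size matched on mean expression in 20 bins. This describes these libraries and is not a test over animals. Of 1000 random lists of 10 genes drawn from the 19989 measured genes, 5.6% lay outside the central 95% with no shift added and 96% with a log2 shift of 0.5. These lists came from the same pool as the lists they were placed among, so the share with no shift follows from construction. It gives no error rate for the fixed lists, whose members can move together. A first run, with 100 other random lists and no shift, had placed 11 outside, and the number of lists was raised after that result was seen. The list of Cajal-Retzius markers had fewer than 4 measured members and was left out of this comparison. Counts of genes that passed the test are given over all genes and adjusted over the list alone.

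The named genes followed a rule also set before the data were examined: the 10 most abundant nuclear protein-coding genes and the 5 most abundant other genes, every member of lists of 8 or fewer and the highest and lowest member of longer lists, list members that passed the test, the 10 highest and 10 lowest log2 ratios among genes that passed the test with a mean CPM of 1 or more and TPM bounds apart, the 5 genes each way that differed most between quantifiers, and the 5 most abundant genes with another leading transcript. Genes named outside this rule are said to be so, and some genes the rule names are not reported here. Genes were compared between quantifiers where mean TPM was 1 or more, after adding 0.1, and leading transcripts where mean TPM was 5 or more.

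The alternatives tried were other scalings (DESeq2 1.42.0 size factors, library totals, spike-in totals), other count filters, protein-coding genes alone, the second quantifier, other dispersions, TPM bounds in place of the test, other pseudocounts, other minimum levels and each library alone. Calls shared by both quantifiers, and the removal of GC content and length trends from 1 list, were added after the data were seen. These trends were fitted by lowess with a fraction of 0.3 in statsmodels 0.14.6 over 13470 protein-coding genes, and 99.9% of the 19989 measured genes had both values. Transcripts were aligned with BLAST 2.17.0 at a word size of 11 and an e-value of at most 0.001. Retained-intron transcripts were compared with protein-coding transcripts in genes with a mean of 20 or more reads for each kind. Tables were handled in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. The phiX control sequence and 26248 numbered features that name no gene, of the 81881 features in the gene table, were left out of the comparisons.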

Results

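Hippocampal total RNA of 2 adult male mice of the B6CASTF1/J cross was measured as 1 ribosomal RNA-reduced, strand-specific library per animal. Both libraries belong to 1 group, and the labels name no comparison of conditions. The data therefore answer which RNAs the hippocampus of these animals held, at what level, and how far the 2 libraries differed. With 1 library per animal, a difference between the animals cannot be told apart from one of dissection, extraction or library preparation. The depth was 23458117 expected counts in replicate 1 and 29584307 in replicate 2. Coordinates are those of mm10.

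Messenger RNA of nuclear genes took most of the expected counts in both libraries, and the rest was largely mitochondrial RNA, long noncoding RNA and a few small RNAs. Nuclear protein-coding genes took 81.2% of expected counts in replicate 1 (95% Wilson interval 81.1 to 81.2%) and 81.0% in replicate 2 (81.0 to 81.0%), a mean of 81.1% ± 0.131 (SD, n = 2). The 2 mitochondrial ribosomal RNAs took 5.42% (5.42 to 5.43%) and 6.64% (6.63 to 6.65%), and the 13 mitochondrial messenger RNAs 1.35% (1.34 to 1.35%) and 1.85% (1.84 to 1.85%). The class of miscellaneous RNA, which holds the 7SL RNA of the signal recognition particle and the transcription regulator 7SK, took 3.39% (3.38 to 3.40%) and 3.90% (3.90 to 3.91%). Counted by TPM, which raises short RNAs, the same class was 27.8% and 29.9%, and protein-coding genes were 50.8% and 48.5%.

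Long intergenic, TEC and sense-intronic RNA took smaller shares in replicate 2. Long intergenic noncoding RNA took 6.06% of counts in replicate 1 (6.05 to 6.07%) and 4.23% in replicate 2 (4.22 to 4.24%), a mean of 5.15% ± 1.29. Gm42418 alone took 1.19% and 0.262%, and the class without Gm42418 took 4.87% and 3.97%. Loci annotated as TEC, transcribed regions that await experimental study, took 0.362% (0.359 to 0.364%) and 0.179% (0.177 to 0.180%). Sense-intronic RNA took 0.0629% (0.0619 to 0.0639%) and 0.0476% (0.0468 to 0.0484%). The ERCC spike-ins took 0.210% (0.208 to 0.212%) and 0.243% (0.241 to 0.244%), a mean of 0.226% ± 0.0232, from 49222 counts on 58 spike-ins and 71775 counts on 64. Of 55536 annotated genes, 14884 had TPM of 1 or more in both libraries, and 13029 of these were protein-coding. The remaining 1855 detected in both compare with 3057 such genes in replicate 1 and 2146 in replicate 2.

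**Figure D1:**
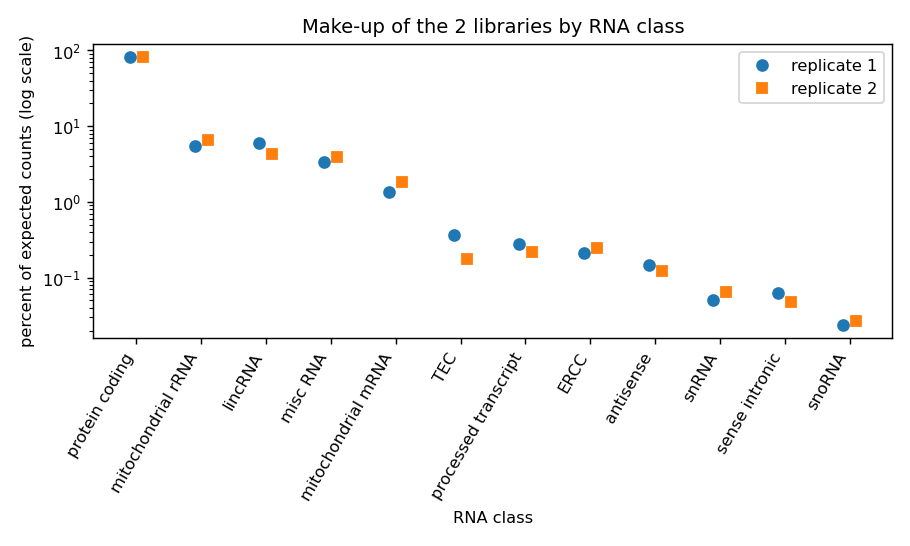
Share of expected counts (percent, log axis) of 12 RNA classes in replicate 1 (circles) and replicate 2 (squares), 1 library each. Protein-coding RNA lay at 81.2% and 81.0%, while long intergenic noncoding RNA (6.06% and 4.23%) and TEC loci (0.362% and 0.179%) lay lower in replicate 2.

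The most abundant nuclear messenger RNAs served iron storage, the synapse, glycolysis and the cytoskeleton. Fth1, the ferritin heavy chain, was at 1583 ± 117 TPM (SD, n = 2, as for all levels) and Camk2a, the alpha subunit of the calcium/calmodulin-dependent kinase of excitatory synapses, at 1496 ± 38.6. Their order was not the same in both libraries: Camk2a (1524) exceeded Fth1 (1500) in replicate 1, and by the second quantifier Gapdh was above both (1867 and 2043). The glycolytic enzymes Gapdh (1486 ± 59.7) and Aldoa (1368 ± 52.2), the actin gene Actb (1461 ± 94.1), the prohormone-processing enzyme Cpe (1345 ± 55.4), the elongation factor Eef1a1 (1277 ± 63.7), the protease inhibitor Cst3 (1109 ± 84.6) and the vesicle fusion protein Snap25 (1048 ± 28.3) were also among the 10 highest. Outside this class, the 7SL genes Rn7s1 and Rn7s2 had identical values of 128798 ± 7830 TPM, so their split is set by the program and is uncertain. The mitochondrial ribosomal RNAs mt-Rnr2 (46804 ± 4344) and mt-Rnr1 (32021 ± 3235) and the 7SK gene Rn7sk (30340 ± 252) followed.

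The median member of the lists for glutamatergic neurons (114 TPM), astrocytes (103.8) and oligodendrocytes (74.1) was above that of the endothelial (8.11), mural (3.58), neocortex (10.7), striatum (3.36) and thalamus (2.94) lists, although single members overlapped. The vesicular glutamate transporter Slc17a7 of hippocampal and cortical neurons reached 621 ± 13.4 TPM, against 11.98 ± 1.73 for Slc17a6, and the postsynaptic genes Nrgn (562 ± 24.2) and Itpka (114 ± 2.30) and the transcription factors Neurod6 (91.5 ± 9.77) and Neurod2 (58.5 ± 9.02) lay between. Synaptic vesicle genes ranged from 45.7 ± 1.15 (Stx1a) to 1048 ± 28.3 (Snap25). Among interneuron markers, the neuropeptide Cck was highest at 260 ± 11.2 and the transcription factor Dlx1 lowest at 7.13 ± 0.396. The astrocyte glutamate transporter Slc1a2 (827 ± 42.0), the myelin gene Mbp (845 ± 14.8) and the lipid carrier Apoe (989 ± 65.4), listed with reactive glia, were each the highest of their list. The lowest members of the astrocyte and oligodendrocyte lists were Aldh1l1 (21.5 ± 0.580) and Opalin (7.15 ± 1.83), and Cst7 of the reactive glia list had no reads. In microglia, Aif1 (4.14 ± 0.0849) was the lowest listed gene. Oligodendrocyte precursors were represented by Pdgfra (17.0 ± 0.834), Gpr17 (11.3 ± 3.82), Cspg4 (7.86 ± 1.12), C1ql1 (6.82 ± 0.00), Vcan (6.71 ± 1.33) and Neu4 (3.93 ± 0.0707). Endothelial markers ran from Ly6c1 (29.3 ± 2.07) down to the VEGF receptor Kdr (3.52 ± 0.714), and mural markers from Rgs5 (25.02 ± 0.912) to Kcnj8 (0.825 ± 0.0778).

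Genes marking each hippocampal subfield were present in both animals. In CA1, Mpped1 (96.3 ± 5.69 TPM), Wfs1 (83.0 ± 4.95) and Fibcd1 (52.0 ± 2.40) led, with Man1a at 33.5 ± 1.06 and Pou3f1 at 20.4 ± 1.11. In CA2, Pcp4 (90.6 ± 3.33) and Rgs14 (43.7 ± 1.48) stood above Amigo2 (10.5 ± 0.226), Cacng5 (5.82 ± 0.686), Ntf3 (4.87 ± 0.0636) and Map3k15 (0.840 ± 0.0141). In CA3, Homer3 (35.6 ± 1.12), Bok (26.4 ± 0.919), Grik4 (26.2 ± 2.52) and Nectin3 (26.1 ± 3.96) were close together, and Coch (1.85 ± 0.0212) and Iyd (1.71 ± 0.184) were low. In dentate granule cells, C1ql3 (64.5 ± 3.30), the granule cell transcription factor Prox1 (33.1 ± 6.05), C1ql2 (32.9 ± 2.45) and Lct (24.1 ± 5.98) exceeded Plk5 (14.3 ± 5.16), Glis3 (11.8 ± 3.76), Dsp (4.31 ± 0.651) and Tdo2 (4.29 ± 0.00707). Of the neurogenic lineage list, Dcx was at 6.06 ± 2.07 and Sox11 at 5.64 ± 1.61, while the dividing-cell genes Mki67 (0.430 ± 0.184) and Top2a (0.330 ± 0.0141) and the progenitor genes Igfbpl1 (0.415 ± 0.290), Neurog2 (0.30 ± 0.141) and Eomes (0.135 ± 0.0636) were under 1 TPM. Reln, the secreted protein of Cajal-Retzius cells that interneurons also make, was at 20.5 ± 1.97, and of the other Cajal-Retzius markers Ndnf was at 10.3 ± 3.04, Trp73 at 1.25 ± 0.219, Lhx1 at 0.040 ± 0.0283 and Lhx5 at 0.0250 ± 0.0354.

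Markers of tissue next to the hippocampus ranged from near 0 to the level of subfield markers. Neocortical Tshz2 (40.3 ± 1.77), Fezf2 (22.6 ± 1.29), Rorb (10.7 ± 0.516), Scnn1a (2.53 ± 0.318) and Foxp2 (1.08 ± 0.191), striatal Ppp1r1b (32.3 ± 8.66), Rgs9 (6.14 ± 0.573), Drd1 (5.42 ± 0.460), Tac1 (2.89 ± 0.438), Drd2 (1.69 ± 0.382), Gpr6 (0.720 ± 0.00) and Adora2a (0.505 ± 0.0495), and thalamic Prkcd (15.4 ± 2.21), Tcf7l2 (5.0 ± 0.0566), Lef1 (2.94 ± 0.615), Slitrk6 (0.415 ± 0.149) and Gbx2 (0.0150 ± 0.0212) were measured in TPM. Some of these genes are also made inside the hippocampus, so the values do not measure a share of another tissue. The Y-linked genes Eif2s3y (35.9 ± 10.3), Ddx3y (21.3 ± 1.49), Uty (12.8 ± 2.28) and Kdm5d (8.54 ± 2.98) were present in both animals, and the X-inactivation RNAs Xist (0.0200 ± 0.00) and Tsix (0.250 ± 0.0141) were near 0.

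Within the transmitter receptor families, 1 or a few subunits carried most of the message. Among AMPA receptor subunits, which carry fast excitation, Gria1 (362 ± 3.37 TPM) and Gria2 (312 ± 54.6) were not separated by the TPM bounds of both libraries, and both lay above Gria3 (85.9 ± 18.5) and Gria4 (28.8 ± 2.18). Among NMDA receptor subunits, the obligatory Grin1 (197 ± 25.5), Grin2a (176 ± 42.4) and Grin2b (138 ± 28.6) overlapped in their bounds from each to the next, while Grin2c (20.8 ± 0.0707), Grin3a (16.8 ± 0.255), Grin2d (4.35 ± 0.148) and Grin3b (0.040 ± 0.0141) followed in separate steps. Among kainate receptor subunits every step was separated: Grik5 (102 ± 8.70), Grik2 (42.3 ± 11.5), Grik4 (26.2 ± 2.52), Grik3 (13.5 ± 2.03) and Grik1 (7.93 ± 0.226). The metabotropic receptor Grm5 (120 ± 13.4) lay above Grm3 (34.7 ± 3.59) and Grm7 (34.3 ± 6.58), which were not separated, and Grm2 (27.4 ± 0.891). Grm4 (5.68 ± 0.495) and Grm8 (5.21 ± 1.09) were lower. Grm6, a retinal receptor, had no reads by the first quantifier and 0.013 TPM in replicate 2 by the second. Among GABA-A receptor subunits, the cerebellar subunit Gabra6 (0.0150 ± 0.0212) was lowest. The same member led in 5 of 5 families with the second quantifier.

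**Figure D2:**
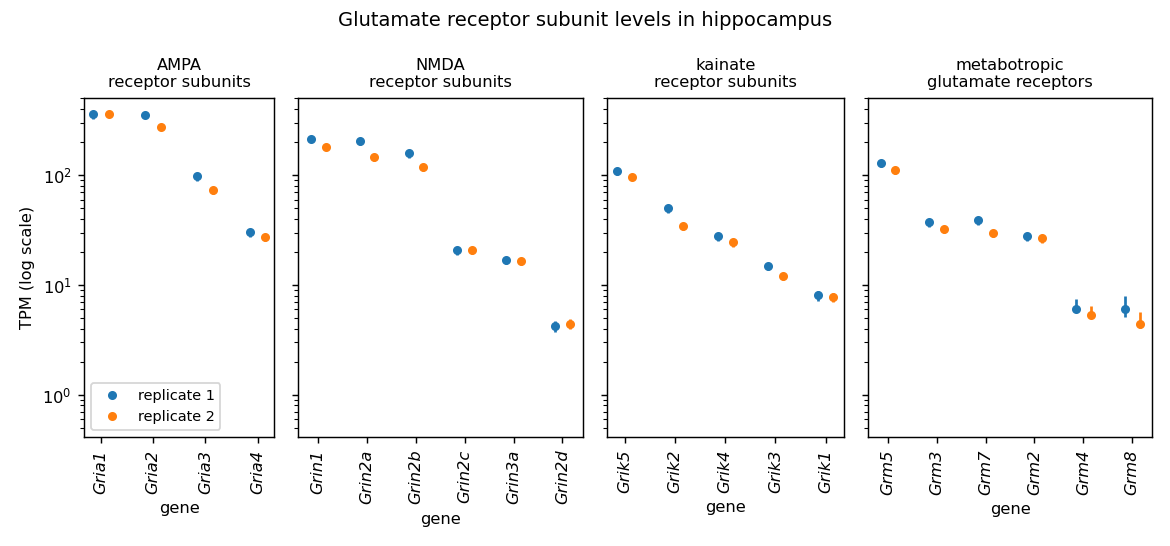
TPM (log axis) of glutamate receptor subunits of 4 families in replicate 1 and replicate 2, with points for the deposited TPM and vertical bars for the deposited credible bounds. The bounds need not contain the point. Grin3b and Grm6, under 0.1 TPM on average, are not drawn; Gria1 (362 ± 3.37), Grin1 (197 ± 25.5), Grik5 (102 ± 8.70) and Grm5 (120 ± 13.4) were the highest of each family.

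Genes that passed the test with TPM bounds apart and a mean CPM of 1 or more were ranked by log2 ratio. Ttr had the highest ratio of replicate 2 over replicate 1. Ttr, Slc4a5, Folr1 and Clic6 are on the fixed list for the choroid plexus, the epithelium that makes cerebrospinal fluid. F5, Mfrp, 1500015O10Rik and Kcne2, which also ranked high, are not on that list, and their tissue of origin was not tested. The pseudogenes Gm15899 (log2 5.122) and Ywhaq-ps3 (4.985) ranked high as well. Ttr (transthyretin, ENSMUSG00000061808.4, chromosome 18, 20665280 to 20674321), the carrier of thyroid hormone in cerebrospinal fluid, had 133 counts in replicate 1 and 35173 in replicate 2, or 8.68 and 1703 TPM, a log2 ratio of 7.71 (edgeR, adjusted p = 1.34e-98). The coagulation factor F5 (log2 5.42, adjusted p = 4.66e-30), the bicarbonate transporter Slc4a5 (5.55, 2.25e-14), Mfrp (5.03, 8.48e-16), the chloride channel protein Clic6 (4.63, 8.62e-17) and 1500015O10Rik (4.56, 3.71e-08) were also higher in replicate 2. The folate receptor gene Folr1 had 3 counts against 224, a ratio of 60.1 with a counting interval of 20.3 to 293 (adjusted p = 5.34e-08). Its TPM of 0.25 in replicate 1 lay below its own bounds of 1.21 to 3.75, so the size of this ratio is uncertain. The potassium channel subunit Kcne2 had 0 counts against 132, at least 35.4-fold higher in replicate 2 (adjusted p = 5.15e-07). Lower in replicate 2 were the mitochondrial leucyl-tRNA synthetase gene Lars2 (ENSMUSG00000035202.8, chromosome 9, 123366927 to 123462666), with 31431 counts against 1406 (log2 -4.79, adjusted p = 1.69e-49), and the long noncoding RNA Gm42418 (ENSMUSG00000098178.1, chromosome 17, 39846958 to 39848788), with 278533 against 77413 (-2.16, 2.42e-08). Whether the reads at Lars2 and Gm42418 come from ribosomal RNA-like sequence was not tested here, so both values are uncertain as levels of these genes. Lower too were the death receptor Tnfrsf25 (-2.13, adjusted p = 1.21e-06), the adaptor gene Dok3 (-1.81, 0.0156), the TEC loci Gm42993 (-1.98, 0.000474), AC154542.1 (-1.90, 0.0379) and 2900027M19Rik (-1.85, 0.00371), and Gm44597 (-1.83, 0.0210).

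The choroid plexus markers Kl, Sostdc1, Kcnj13 and Aqp1 were among the 60 genes higher in replicate 2, and the activity-regulated gene Arc and the imprinted antisense RNA Kcnq1ot1 among the 70 lower. In all, 130 of 16123 tested genes passed the edgeR test, and 778 had an unadjusted p under 0.05. Of the 130, 82 were protein-coding, and the 9 TEC loci were all lower in replicate 2. With the second quantifier, 57 of the 130 also passed, 54 of them in the same direction (27 higher and 27 lower) and the rest in the opposite direction. Split by size instead, 62 were 2-fold or more in the same direction by the second quantifier, 37 were under 2-fold or opposite, and 31 were not tested. The 54 and the 37 overlap, because a gene can pass with both quantifiers at under 2-fold. Slc4a2, named after its value was seen, did so (log2 0.94 and 0.96). Among the genes named by the rule, Gm15899, Ywhaq-ps3, Rps27a-ps2 and Gm20521 were not tested with the second quantifier and are uncertain, and the first 3 are annotated as pseudogenes. Gm14760, named after its value was seen, had 619.7 counts against 0, at least 257-fold lower in replicate 2, but its TPM bounds overlapped and the second quantifier gave it 0. By the first quantifier Gm15899 was at least 20.04-fold and Ywhaq-ps3 at least 18.3-fold higher in replicate 2, and Rps27a-ps2 (log2 -2.91) and Gm20521 (-2.23) were lower. Over the alternatives, adjusted p ranged from 0.000124 to 0.0589 for Gm20521, from 0.00165 to 0.0989 for AC154542.1, from 0.000944 to 0.108 for Dok3, from 0.00242 to 0.166 for Gm44597 and from 3.31e-07 to 0.0834 for Kcnq1ot1, so these did not pass under each of them.

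Most tested genes, Fth1 and Camk2a among them, lay within 2-fold between the libraries, while others differed by more without passing the test. Across 55536 genes, those that passed included, Pearson's r of log2(TPM + 1) was 0.988 and Spearman's rho 0.933. The biological coefficient of variation, here the spread between the 2 libraries from any source beyond counting error, was 0.191. Of the tested genes, 85.9% lay within 1.5-fold and 93.2% within 2-fold, and 1102 were 2-fold or more apart. The 21 spike-ins with 200 or more reads had a median log2 ratio of 0.19 (SD 0.15) per total count.

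**Figure D3:**
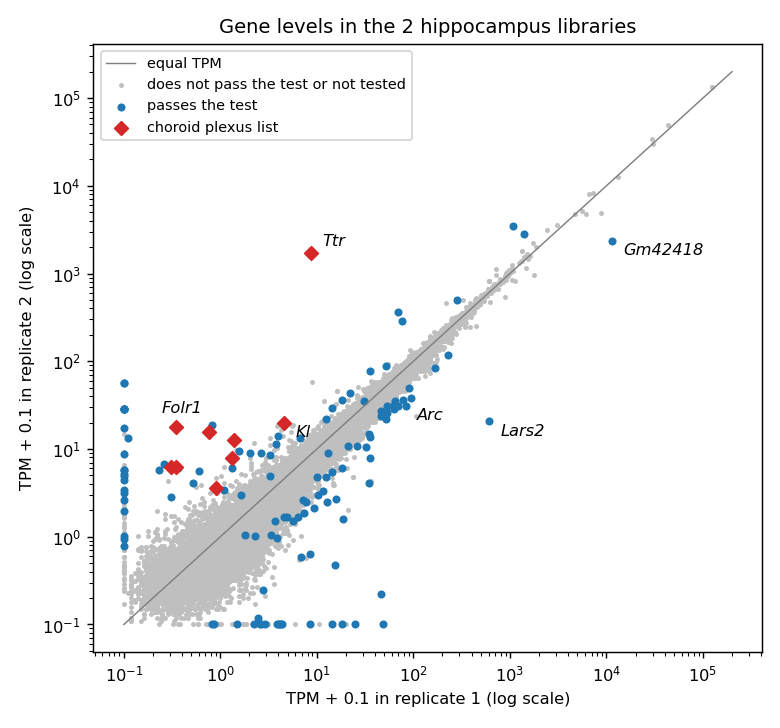
TPM + 0.1 in replicate 1 (horizontal, log axis) against replicate 2 (vertical, log axis) for each gene with 10 or more reads in all; blue points passed the edgeR test, red diamonds are the choroid plexus list and the line marks equal values. The diamonds lie above the line, led by Ttr (8.68 and 1703 TPM), while Lars2 (610 and 20.7 TPM) and Gm42418 (11410 and 2351 TPM) lie below it.

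Of 38 gene lists, 10 had a median log2 ratio above the central 95% of matched random lists and 6 below it. The choroid plexus list stood out: its median was 4.49 (random lists -0.47 to 0.24), all 9 members were above 0, 8 passed the test over all genes and 9 adjusted over the list alone. Besides Ttr, Folr1, Clic6 and Slc4a5 these were Kl (log2 2.24), Kcnj13 (3.30), Aqp1 (4.48) and Sostdc1 (4.49), and the transcription factor Otx2 passed over the list alone (2.87, adjusted p = 0.0567 over all genes). Ependymal markers, from the ciliated cells that line the ventricles, had a median of 0.66, and 0 of 4 tested passed either way: Foxj1 was at 0.47, Rarres2 at 0.36, Ccdc153 at 0.86, Tekt1 at 1.21 and Tmem212 at -0.29, and Dynlrb2 had 0 and 18 counts. With Dynlrb2 at its bound the median was the same, 0.66. Striatal markers had a median of 0.45, mural cell markers 0.33, interferon-responsive genes 0.32, microglia markers 0.19 and interneuron markers 0.19 (the last 2 below 0 but still outside the random lists when scaled by spike-ins), each with 0 genes that passed over all genes or over the list alone. Among mural markers, the contractile genes Acta2 (0.59), Tagln (0.77) and Myh11 (0.59) were above Pdgfrb (0.33) and Rgs5 (0.11), with Abcc9 at 0.16. Among interferon-responsive genes, Ifi27 (61.6 ± 5.54 TPM) was the highest and Usp18 (0.115 ± 0.0778) the lowest.

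Mitochondrial and ribosomal messages lay higher in replicate 2 than matched random lists, by less, with TMM and with spike-in scaling. The 13 mitochondrial messenger RNAs had a median of 0.36, with 12 above 0. Of these mt-Co3 (1.81, adjusted p = 9.05e-08), mt-Atp6 (1.14, 0.00476) and mt-Co2 (0.95, 0.000491) passed over all genes and over the list alone. None of the 3 passed with the second quantifier, and over the alternatives adjusted p ranged from 8.37e-23 to 1.0, from 9.96e-09 to 0.871 and from 0.000474 to 0.724. The most abundant of the list, mt-Co1 (7279 ± 955 TPM), was at 0.39 and mt-Nd6 (188 ± 36.5) at 0.52. Cytosolic ribosomal protein genes had a median of 0.20, with 72 of 76 above 0. Of these only Rpl10 passed (0.95, adjusted p = 0.0159, 1 over the list alone), and over the alternatives its adjusted p ranged from 0.0153 to 1.0. Rpl41 was the highest at 615 ± 5.37 TPM, and Rpl10l had no reads. Replication-dependent histone genes, measured as their RNAs lack a poly(A) tail and total RNA retains them, had a median of 0.20 with 39 of 58 above 0 and the same median with members at 0 set to their bounds, led by Hist1h4h (142 ± 5.23 TPM). Of these Hist1h2ai alone passed, in the opposite direction, with 74.5 counts against 0, at least 30.9-fold lower in replicate 2. It is one of many similar histone genes and is uncertain: over the alternatives its adjusted p ranged from 5.03e-13 to 1.0, the highest with the second quantifier. Scaled by spike-ins, the median of all tested genes moved to -0.23, and the medians of the ribosomal protein (-0.03), histone (-0.02), microglia (-0.03) and interneuron (-0.04) lists turned below 0, as did those of CA1, CA2, CA3, glutamatergic neuron, synaptic vesicle, neurogenic, GABA-A receptor, astrocyte, oligodendrocyte, reactive glia, endothelial, meningeal, neocortex, thalamus and imprinted genes. This shift moves all genes alike, and among random lists the ribosomal protein, histone, microglia and interneuron lists kept their place at percentiles 100, 100, 98.9 and 99.1. The choroid plexus (4.27), ependymal (0.44), striatum (0.23), mitochondrial (0.13), interferon (0.11) and mural (0.10) lists stayed above 0.

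Long noncoding RNAs held in the nucleus and genes of recent neuronal activity lay lower in replicate 2. All 7 nuclear long noncoding RNAs were below 0, with a median of -0.79 (random lists -0.12 to 0.17). The imprinted Kcnq1ot1 (-1.22, adjusted p = 6.11e-07) passed over all genes, and 5 passed adjusted over the list alone, with Meg3 (-0.82), Malat1 (-0.82), Snhg11 (-0.79) and Miat (-0.66). Rian was at -0.28 and Neat1 at -0.20. Malat1 stood at 8836 TPM in replicate 1 and 4889 in replicate 2. Of the 20 genes on the immediate early list, which holds genes that respond to neuronal firing, 19 were below 0, with a median of -0.39. Arc, a regulator of AMPA receptor traffic, had 82.9 TPM in replicate 1 and 30.8 in replicate 2 (-1.31, adjusted p = 6.97e-08). It alone passed over all genes, and 3 passed adjusted over the list alone, with Fos (-1.42) and Nr4a1 (-0.78), named after their values were seen. Homer1 (-0.44) was the most abundant of the list and Egr2 (-1.41) the least, and neither passed.

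Glucocorticoid-responsive genes had a median of -0.29, with 10 of 10 below 0, 0 that passed over all genes and 1 adjusted over the list alone, the lipid droplet gene Plin4 (-1.09), named after its value was seen. Zbtb16 (62.9 ± 12.7 TPM) was the most abundant and Sult1a1 (3.09 ± 0.233) the least. Heat shock genes had a median of -0.30 with 9 of 11 below 0, from Hspa8 (979 ± 223 TPM, log2 -0.22) to Bag3 (6.85 ± 1.39, -0.30), and 0 passed either way. Blood markers had a median of -0.32, with the globin genes Hbb-bs (145 ± 38.6 TPM), Hba-a1 (128 ± 27.4), Hba-a2 (112 ± 25.2) and Hbb-bt (12.96 ± 1.20) and the heme synthesis enzyme Alas2 (1.80 ± 0.488) all below 0. Hba-a1 and Hba-a2 are near-identical, so their split is uncertain. Dentate granule markers had a median of -0.22, and 0 of either list passed over all genes or over the list alone. Blood markers were no longer outside the random lists under 4 of 5 alternatives, and neither were dentate granule (percentile 3.05), striatum (median 0.07, percentile 94.4) and interneuron markers (median 0.02, percentile 93.3) with the TPM ratio.

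The remaining 22 lists lay inside the central 95%, and 5 of them lay outside under 1 alternative: CA2 (percentile 98.3) and glutamatergic neurons (98.4) with the second quantifier, CA1 (98.5) and oligodendrocytes (98.8) with the TPM ratio, and sex-linked genes (0.43) at a mean CPM of 1 or more. Medians of subfield and neuron lists were 0.15 for CA1, 0.12 for CA2, 0.13 for CA3, 0.17 for glutamatergic neurons, 0.13 for synaptic vesicle genes and 0.03 for the neurogenic lineage. Receptor families lay at -0.13 for AMPA, -0.02 for NMDA, -0.03 for kainate, -0.09 for metabotropic glutamate and 0.12 for GABA-A receptors. Glial and vascular lists lay at 0.10 for astrocytes, 0.12 for oligodendrocytes, -0.17 for their precursors, 0.18 for reactive and aged glia and 0.10 for endothelium. Neocortex was at 0.02, thalamus at 0.16 and the sex-linked genes at -0.16, with 1 gene, Kdm5d (-0.77), that passed adjusted over the list alone. Meningeal fibroblast markers were at 0.07, with Dcn at 0.23, Slc6a13 at 0.10, Col1a2 at 0.03, Col1a1 at -0.08, Lum at 0.07 and Col3a1 at -0.28. In this list the growth factor gene Igf2 alone passed (35.2 and 77.2 TPM, log2 1.15, adjusted p = 2.83e-05, 1 over the list alone), and its adjusted p over the alternatives ranged from 2.35e-05 to 0.330, the highest with spike-in scaling. Imprinted genes were at 0.02, with 2 that passed over all genes (Igf2 and Kcnq1ot1) and 4 adjusted over the list alone (with Meg3 at -0.82 and Mirg at -0.62, the latter named after its value was seen). Levels ran from Meg3 (1383 ± 579 TPM) to H19 (0.0600 ± 0.0141). Circadian clock genes were at -0.01, with 0 that passed over all genes and 2 over the list alone, Dbp (0.69) and Per3 (-0.66), named after their values were seen. Levels ran from Tef (142 ± 25.6 TPM) to Cry1 (7.60 ± 0.870). In the lists not given a count here, 0 genes passed over all genes or over the list alone.

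**Figure D4:**
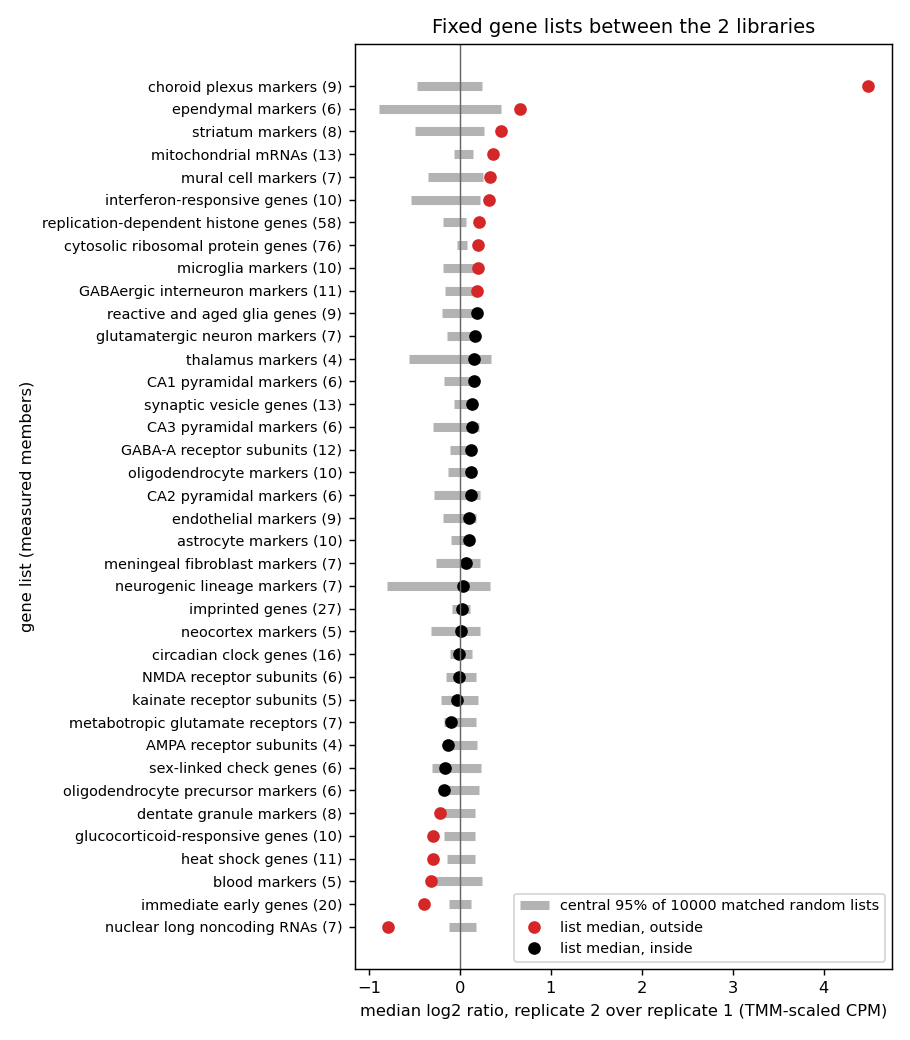
Median log2 ratio of replicate 2 over replicate 1 (TMM-scaled) of 38 gene lists, with the number of measured members in brackets; grey bars span the central 95% of 10000 matched random lists and red points lie outside them. Choroid plexus markers (4.49) lie farthest above and nuclear long noncoding RNAs (-0.79) farthest below.

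The 2 deposited quantifications of the same reads parted most often, but not only, at short genes. Rmrp (1302 ± 218 TPM by the first quantifier), the RNA of the RNase MRP enzyme, Snurf (959 ± 68.2), which shares its locus with Snrpn, the small nuclear RNA genes Gm24407 (922 ± 291) and Gm24265 (837 ± 180) and Rprl3 (668 ± 19.3), a gene related to the RNase P RNA, had 0 TPM by the second. In the other direction stood Gm7336 (4.65 and 6.34 TPM by the first, 442 and 443 by the second), Gm8797 (7.69 and 10.9 against 404 and 370), Hist1h2ai (18.0 and 0 against 61.0 and 31.6), the ATP synthase subunit gene Atp5g2 (4.85 and 4.18 against 80.7 and 90.8) and Gm45234 (2.5 and 0 against 8.32 and 10.1). The levels of these 10 genes are uncertain, and the cause of the difference was not tested. In all, 572 of 16024 genes differed 2-fold or more the same way in both libraries, 108 higher and 464 lower by the second quantifier, and judged from a single library 863 did so in replicate 1 and 782 in replicate 2, the 572 included. The share was 42.1% of genes under 500 bases, 6.91% from 500 to 1000 bases and 0.673% of longer genes. It was 66.4% of small nucleolar RNA genes, 38.2% of processed pseudogenes and 0.660% of protein-coding genes.

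The leading transcript of a gene also depended on the quantifier. Of 10021 genes with mean TPM of 5 or more and several transcripts, 773 (7.71%) had 1 leading transcript in both libraries by the first quantifier and another by the second. In Gapdh, the first gave 68.6% ± 0.638 of the gene's TPM to Gapdh-208, a processed transcript, and the second gave 48.3% ± 0.460 to the protein-coding Gapdh-207. In Syp, a synaptic vesicle gene, Syp-201 had 55.7% ± 1.40 by the first and Syp-202 had 54.6% ± 1.08 by the second. In the ubiquitin gene Ubb, Ubb-201 had 59.2% ± 0.473 by the first and Ubb-202 had 55.8% ± 0.834 by the second. Snhg14 (46.6% ± 3.95 for Snhg14-203 against 29.3% ± 2.43 for Snhg14-205) and Ndrg4 (37.2% ± 5.55 for Ndrg4-202 against 29.2% ± 2.55 for Ndrg4-210) parted likewise. With a lead of 10 percentage points or more required of both, 254 genes remained.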

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

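No test in this part was chosen after the result was seen. Counts appeared in features that no comparison used, above the 3 counts that a count of 0 allows in a library. The phiX sequence, a bacteriophage genome used as a sequencing control, had 51 expected counts in replicate 1 and 86 in replicate 2. The 26248 numbered features that name no gene, of which 63 had an effective length above 0, had 5.92 and 4.92 expected counts together, a sum over features set against the limit for a single count of 0. What these features are is not given in the sources used here, and no explanation was tested.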

How the results depend on the processing

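The calls shared by both quantifiers and the subtraction of GC content and length trends were chosen only after the data were seen. Of 50 values of the summary results under the alternatives, 33 stayed near the reported value and 17 moved. The protein-coding share was 49.7% by TPM, which by construction raises short RNAs. The correlation was 0.978 with a pseudocount of 0.1 and 0.966 over genes with mean TPM of 1 or more. The coefficient of variation was 0.244 with spike-in scaling, 0.202 without the count filter, 0.151 with a minimum of 5 CPM, 0.138 over protein-coding genes and 0.219 with the second quantifier. The count of genes that differed was 91 to 135 under the other scalings, filters, gene types, the second quantifier and the DESeq2 trend. It was 341 (81 higher and 260 lower in replicate 2) with a common dispersion. By TPM bounds with a log2 ratio of 1 or more it was 862 (80 and 782), which held 63 of the 130. With both quantifiers, 54 passed in the same direction. The quantifiers differed for 920 genes at 1.5-fold, 309 with mean TPM of 5 or more, 88 among protein-coding genes and 782 to 863 without a replicate, by construction of wider or narrower sets. Another leading transcript was found for 254 genes when a lead of 10 points was required, and the spike-in share was 0.191% with the second quantifier. Apart from the values said to follow from construction, the cause was not tested. Without a replicate, detected genes ranged from 15452 to 16417, the protein-coding share from 81.0 to 81.2% and the spike-in share from 0.210 to 0.243%, and the leading receptor subunit was the same in 5 of 5 families. The correlation, dispersion, differing genes and lists need both libraries, so they have no value without a replicate. Of 271 values for 32 named genes, 246 stayed on their side of the threshold in the same direction, 25 no longer passed and 0 reversed, and 21 genes passed under every alternative that tested them. Of 81 values for the 16 lists outside the random lists, 74 stayed outside, 7 did not and 0 changed side, and the interneuron, blood, dentate granule and striatum lists each lost their place under at least 1 alternative. Of the 22 lists inside, 5 lay outside under at least 1 alternative. No paired analysis was possible because there is only 1 group. Depth limits the test to genes with 1 or more CPM in a library, and 123 genes passed without that filter.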

Other observations

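The tests of the Ttr pattern were chosen only after the result was seen, as were the genes of the next paragraph and the comparison of the lncRNA list with and without GC content and length trends.

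Genes outside the choroid plexus list also passed the edgeR test with both quantifiers. Those named here were picked one by one. Neither a shared function nor a shared tissue of origin with the choroid plexus list was tested. Enpp2, the secreted lysophospholipase autotaxin, was higher in replicate 2, with 68.9 TPM in replicate 1 and 369 in replicate 2 (log2 2.55, adjusted p = 4.10e-19). The angiotensin-converting enzyme Ace (2.12), the prolactin receptor Prlr (2.31), the tight junction gene Cldn2 (3.64), the collagen gene Col8a1 (3.66) and the insulin-like growth factor-binding protein Igfbp2 (1.16) differed in the same direction. Lower in replicate 2 were the splicing regulator Tra2a (-0.998), the cyclophilin Nktr (-0.92) and the long noncoding RNAs Lncpint (-1.27) and Ftx (-0.94).

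Ttr was at 8.68 TPM in replicate 1 and 1703 in replicate 2. The other 8 members of the choroid plexus list were all 2-fold or more higher in replicate 2, from log2 2.24 to 5.55, with a median of 4.48. The lowest median of the list over 4 scalings was 4.27. Each scaling moves all genes alike, and the median of all tested genes ranged only from 0 to -0.23. This check of scaling between libraries could therefore hardly have come out otherwise, and no conclusion is drawn from it. Choroid plexus tissue taken along with 1 hippocampus is a candidate explanation. In replicate 2, 9 of the 9 members reached 1 TPM, and in replicate 1, 4 did, which restates the same difference. That 0 are on another list follows from how the lists were written. Whether the dissection or the animals differed stays open, and no biological explanation was tested because the labels give 1 group.

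Lars2 and Gm42418 were both lower in replicate 2, with log2 ratios of -4.79 and -2.16. Reads of 1 sequence counted at both genes are argued against, since at an e-value of at most 0.001 the longest alignment of 90% identity between their transcripts, or with Gm26917, was 0 bases. By the first quantifier, Lars2-209 took 97.54% of the Lars2 reads in replicate 1 and 61.2% in replicate 2. The other transcripts together had a log2 ratio of -0.84 by that quantifier. The 2-fold limit set beforehand for reads from 1 part of Lars2 was for transcripts that lack that part. Of the 774 counts of the other transcripts in replicate 1, 734 were on Lars2-201. Lars2-201 and Lars2-209 share 3751 bases, 99.9% of Lars2-209, so the limit was not tested as set and the split of reads between them is open. Reads from 1 part of Lars2 therefore cannot be told apart from a change of the whole gene. The condition on shared sequence was added after the transcripts were aligned. The second quantifier gave Lars2-205 5486 reads in replicate 1 and 308 in replicate 2 where the first gave 0. By the second quantifier this transcript differed by more than 2-fold, so the value of -0.84 rests on the first quantifier. Whether the reads at both genes come from ribosomal RNA-like sequence was not tested, as no genome sequence was used here, nor was any biological explanation.

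All 7 nuclear long noncoding RNAs were lower in replicate 2, with a median log2 ratio of -0.79. Over protein-coding genes the log2 ratio was only weakly related to GC content (r = 0.022) and log2 transcript length (r = -0.091). Trends fitted on those genes did not account for the whole difference. The median was -0.56 after those trends were subtracted, against -0.08 to 0.17 for the central 95% of random lists. Whether noncoding RNAs follow the same trends was not tested, so a GC content or length bias particular to them stays open. Within 5243 genes, retained-intron transcripts were lower in replicate 2 against the protein-coding transcripts of the same gene by a median log2 difference of -0.65, with 84.4% of genes below 0. This is consistent with less nuclear or incompletely spliced RNA in replicate 2 as a candidate explanation, and the second quantifier gave -0.66 over 5455 genes. Whether extraction, library preparation or the animals differed stays open, and no biological explanation was tested.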
